A study of Mus musculus with 19 samples.

How the data were processed

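Striatal RNA was sequenced from 19 male mice aged 4 months. The animals carried Cre recombinase under control of the dopamine D2 receptor gene and a Cre-dependent Cas9 linked to EGFP, so that Cas9 cuts only in D2 receptor cells that also receive a guide RNA. An adeno-associated virus was injected into the medial prefrontal cortex, carrying either guide RNAs against the D2 receptor gene Drd2 (the knockout mice) or mCherry alone (the control mice). Beginning 3 weeks later, mice received saline on 5 days with locomotion recorded for 30 min, and on day 9 a challenge of saline or of amphetamine at 3 mg/kg. Tissue was taken 90 min after the challenge according to the labels' protocols, which give that time for the amphetamine mice and do not state it separately for saline. The groups were taken from the sample titles and treatment labels: 5 saline control mice, 5 amphetamine control mice, 5 saline knockout mice and 4 amphetamine knockout mice. A KO library 7 that the authors' table of the knockout amphetamine comparison names as left out was not analysed here.

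The authors deposited whole-number gene counts for each mouse, made with HTSeq 0.6.1p2 per the submitters' processing notes, which also name FastQC 0.11.5, Trim Galore 0.5.0, STAR 2.6.0c, DESeq2 1.26.0s, R 3.6.1 and the genome build GRCm39 without giving their order or settings. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping or antisense genes and near-identical paralogs can share reads. The authors also deposited 3 comparison tables, for amphetamine against saline in each genotype and for knockout against control under saline. Per the file headers these tables give log2 fold changes with their standard errors from DESeq2. The p-values and adjusted p-values in the deposited tables are also the authors'. The FPKM values in the authors' deposited tables are fragments scaled by gene length and library total, with a gene length that is not stated. They were used only to check that each FPKM column matched the counts of its mouse, with Spearman correlations from 0.954 to 0.958 and 0 genes listed at 0 in only 1 of both. Gene symbols and coordinates came from the deposited tables, which name 22889 genes, and the coordinates refer to GRCm39. The reference genome at hand was of another build and was not used here. The count files held no lines for unassigned reads.

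Library totals ran from 65578294 to 75756345 counts in saline control, from 57003408 to 80857642 in amphetamine control, from 75449097 to 85536346 in saline knockout and from 72759747 to 83149920 in amphetamine knockout mice. At 1 CPM (the usual scaling of a count by its library total) a gene has at least 57 counts in each library. Counting error was not compared with the spread between mice. No 2 libraries were copies of each other, since the smallest chi-square per degree of freedom between any pair was 10.3. Correlations of log2 CPM between libraries ran from 0.970 to 0.994. The first 4 principal components held 18.4%, 12.8%, 10.3% and 8.31% of the variance. Amphetamine knockout libraries 2 and 3, saline knockout library 3 and saline control library 5 were picked by eye as standing apart on them. By distance from the origin, amphetamine control library 3 (57.1) lay farther out than amphetamine knockout library 2 (44.1), and a setting without all 5 was added.

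Counts were tested in R 4.3.3 with edgeR 4.0.16. Of 49592 genes, 21513 passed filterByExpr. They were scaled by TMM and fitted with the quasi-likelihood model (robust settings) as 4 group means over all 19 libraries, so that all groups share an estimate of the spread. The 5 contrasts were amphetamine against saline in each genotype, knockout against control under each treatment, and the difference of the amphetamine response between genotypes. P-values were adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. Adjusted p-values given for single genes are from this edgeR test unless the authors' deposited table is named. The standard error of a log2 fold change was the fold change over the root of its F value. Levels are TMM-scaled CPM as mean ± SD over mice.

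Gene lists, 30 in number, were fixed for striatal cell types, neighbouring tissue, dopamine and acetylcholine signalling, neuronal activity, stress and RNA quality. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01 between genes, adjusted over the 30 lists. Camera with an estimated correlation and fry, which tests whether the members of a list move on balance 1 way and makes no comparison with other genes, were alternatives. The list value is the mean over its members of the difference between group means of log2 CPM. A list score is the mean log2 CPM of its members in a library, and scores were compared by 2-sided exact permutation tests, adjusted over the 30 lists. With 5 mice against 5 or 4 the smallest p these tests can give is 0.00794. A list of hypothalamic neuron genes was added after the principal components had been seen. Several lists share genes, among them the direct-pathway, indirect-pathway, striatal neuron and dopamine lists.

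Genes are named by a rule: called genes with a symbol and a mean of at least 1 CPM in a compared group, up to the 12 largest rises and 12 largest falls; where fewer than 5 genes were called, the 5 smallest p-values; up to 4 members with the smallest p of each list that was called or held a called gene; and always Drd1, Drd2, Chat, Slc18a3, Slc5a7, Fos, Arc, Npas4, Egr1, Pdyn, Penk and Tac1. Groups, tests, lists and this rule were set before the data were examined. So were the alternatives: DESeq2 size factors or upper-quartile factors, DESeq2 1.42.0 on all libraries, limma voom with sample weights, other filters on low counts, only the groups compared, no robust fit, a cortical score or 1 surrogate variable (sva 3.50.0) as covariate, blocks on the mouse number, and leaving out each mouse. After the data were seen, 5 alternatives were added. They leave out the 4 libraries that stand apart, leave out the 5 libraries farthest on the principal components, leave out 2 saline libraries with high glucocorticoid-induced genes, use the cortical, choroid plexus and hypothalamic scores as 3 covariates, or run DESeq2 on the 2 groups compared.

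The scripts were tested on simulated data, drawn from the means and spread of the real libraries with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. In the simulated control amphetamine comparison (21232 genes), edgeR found 52 of the 100 smaller and 94 of the 100 larger changes with 4 unchanged genes called. For amphetamine in knockout mice (21278 genes) it found 39 and 83 with 6 unchanged genes called, for the knockout under saline (21235 genes) 53 and 89 with 7, and for the knockout under amphetamine (21271 genes) 46 and 88 with 6. DESeq2 on the 2 groups found 62 and 98, 48 and 92, 58 and 93, and 62 and 96 of them in the same order, and called 51, 61, 32 and 50 unchanged genes. A list raised in each simulation was called in all 4, with 0, 2, 0 and 0 other lists called. Genes were drawn independently in these simulations, so they do not show how often correlated genes give false list calls. Other splits of the real mice into groups of the same sizes also called lists. Their median was 8 lists for amphetamine in control mice and 12 in knockout mice. It was 9 for the knockout under saline, and 11 for the knockout under amphetamine and for the interaction.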

Results

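Gene counts were available for the striatum of 19 male mice in 4 groups: saline control (n = 5), amphetamine control (n = 5), saline knockout (n = 5) and amphetamine knockout (n = 4). The knockout was aimed at the D2 dopamine receptor gene in D2 receptor cells of the medial prefrontal cortex, where no level was measured, and the tissue sequenced was the striatum, the main subcortical target of dopamine neurons. Each library held between 57003408 and 85536346 counts. The design asks how the striatum responds to an acute dose of amphetamine, which releases dopamine, and whether that response or the saline level differs in mice given the guide RNAs. Between 27591 and 29281 genes per library had at least 1 count. Each mouse is a separate animal according to the labels.

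Drd2 (ENSMUSG00000032259.9, chromosome 9, 49251927 to 49319477), the gene targeted in prefrontal cortex, encodes the D2 receptor and is abundant in striatal indirect-pathway neurons. Its striatal level does not check the knockout, because the virus was placed in another region. Drd2 stood at 125 ± 31.9 CPM (SD, n = 5) in saline control, 173 ± 25.6 CPM (n = 5) in amphetamine control, 105 ± 19.1 CPM (n = 5) in saline knockout and 85.4 ± 40.0 CPM (n = 4) in amphetamine knockout mice. Single libraries ran from 34.1 CPM in amphetamine knockout library 3 to 200 CPM in amphetamine control library 5. By edgeR the Drd2 contrasts were not called in any of the 4 pairwise comparisons, with adjusted p from 0.223 for knockout against control under amphetamine to 0.779 for knockout against control under saline.

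**Figure D1:**
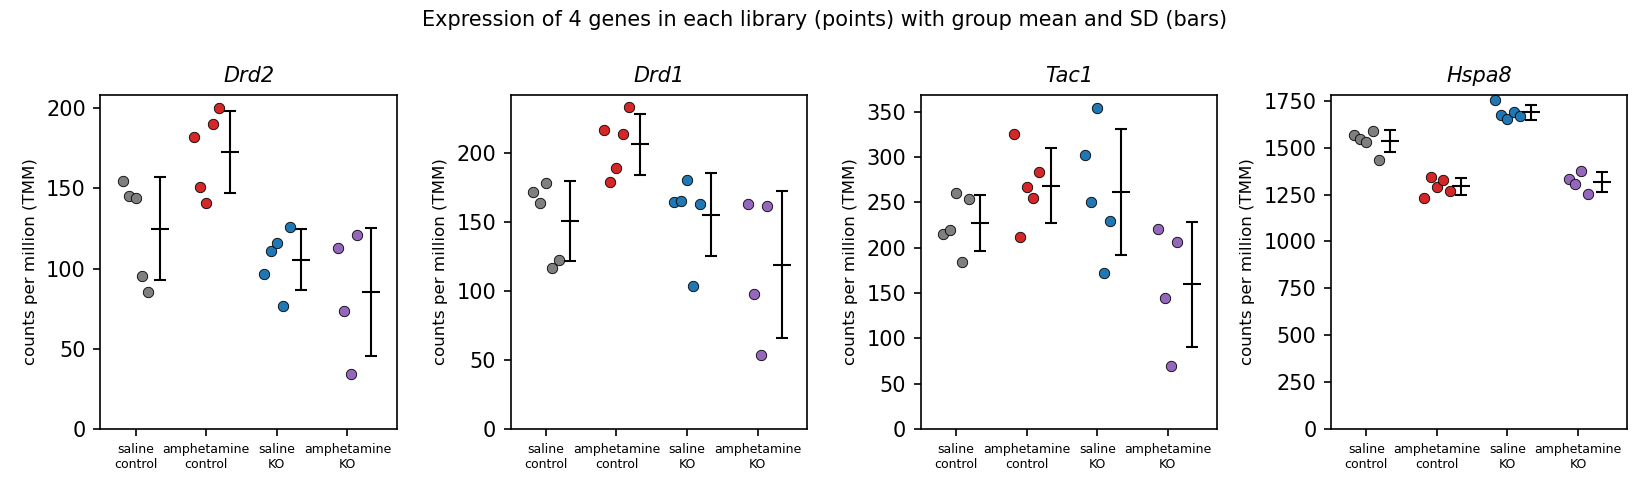
CPM (TMM-scaled, vertical axis from 0) of Drd2, Drd1, Tac1 and Hspa8 in each of the 19 libraries, with points for mice and bars for group mean and SD. Hspa8 averaged 1294 CPM in amphetamine control and 1317 CPM in amphetamine knockout mice against 1535 and 1690 CPM after saline, while Drd2 was lowest in amphetamine knockout library 3 at 34.1 CPM.

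The first comparison asks what amphetamine does in the striatum of control mice. The lists named next were called by camera at the preset correlation, and none was called with an estimated correlation. Transcripts of striatal projection neurons, the GABAergic output cells of the region, were higher after amphetamine by a mean of 0.44 on the log2 scale, with a list score of 8.92 ± 0.149 (SD, n = 5) against 8.48 ± 0.264 (n = 5). Heat shock genes, which encode cytosolic chaperones, were lower by a mean of -0.20, with scores of 6.12 ± 0.0589 against 6.32 ± 0.125. Genes of ciliated ependymal cells, which line the ventricle, were lower by a mean of -0.71, and cortical projection neuron genes were higher by 0.94. Clock genes were higher by 0.18. A single gene passed the test across all genes: Plcd4 (ENSMUSG00000026173.16, chromosome 1, 74582047 to 74606953), which encodes a phospholipase C that cleaves phosphoinositides, fell from 21.8 ± 1.18 CPM (SD, n = 5) to 13.9 ± 0.884 CPM (n = 5), a log2 fold change of -0.65 ± 0.0895 (SE) with an adjusted p of 0.0099 by edgeR.

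The striatal projection neuron list had 14 of 14 members above 0 (camera, adjusted p = 7.5e-07). Its adjusted p was 0.41 with an estimated correlation, and its adjusted exact permutation p was 0.0595. Examples that were not called as single genes were Rasd2, a small G protein of striatal neurons, at 0.59 ± 0.217 (SE), and Bcl11b, a transcription factor that specifies these cells, at 0.45 ± 0.148. Dopamine receptor and transduction genes were higher by 0.30 with 13 of 16 above 0 (adjusted p = 0.000117; adjusted p = 0.474 with an estimated correlation). Rgs4, which shortens G protein signals, stood at 457 ± 45.2 CPM after amphetamine and 306 ± 56.2 CPM after saline, a log2 fold change of 0.58 ± 0.181 with an adjusted p of 0.218. Drd1, the D1 receptor gene of direct-pathway neurons, had a log2 fold change of 0.45 ± 0.228 and Drd2 one of 0.47 ± 0.255. Neither direct-pathway markers (mean 0.19, adjusted p = 0.214) nor indirect-pathway markers (0.28, adjusted p = 0.0617) were called as lists. The indirect-pathway list was called without amphetamine control library 2 (0.32) or 3 (0.31) or saline control library 2 (0.34) or 3 (0.35). No member of these 4 lists passed the test over all genes or adjusted over the list alone.

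Immediate early transcription factors, which neurons switch on within an hour of activity, were higher by a mean of 0.21 with 18 of 24 members above 0 (adjusted p = 0.000666; adjusted p = 0.56 with an estimated correlation). None passed over all genes and 1 did when adjusted over the list alone. The members with the smallest p were Btg2 at 0.52 ± 0.127, Junb at 0.41 ± 0.149 and Ier5 at 0.42 ± 0.159, and the authors' deposited table lists these 3 as higher with adjusted p of 0.00358, 0.0208 and 0.0225. Fos, Npas4 and Egr1, the usual activity markers, were not called, with log2 fold changes of 0.03 ± 0.169, 0.00 ± 0.223 and 0.27 ± 0.201. Activity-induced effector genes were higher by 0.19 (adjusted p = 0.0113; adjusted p = 0.56 with an estimated correlation). Plk2, a kinase that weakens active synapses, stood at 0.49 ± 0.12, and Arc, a postsynaptic protein, at 0.21 ± 0.278. Effector genes were not called without amphetamine control library 4 (0.18), saline control library 3 (0.16) or saline control library 4 (0.14), and the early factors had a mean of 0.33 without saline control library 2. Cortical neuron genes, which express many of the same activity genes, moved in the same direction, and with the 3 neighbouring-tissue scores as covariates, added after the data were seen, the means became -0.09 for the early factors and -0.01 for the effectors.

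Heat shock genes had 13 of 14 members below 0 (adjusted p = 2.82e-05; adjusted p = 0.368 with an estimated correlation). None passed over all genes and 5 were lower when adjusted over the list alone. Hspa8, the constitutive 70 kDa chaperone (chromosome 9, 40712280 to 40721383), went from 1535 ± 59.8 to 1294 ± 44.2 CPM, a log2 fold change of -0.25 ± 0.0586 with an adjusted p of 0.149. Hspa1a, its stress-induced relative and a near-identical copy of Hspa1b with which reads can be shared, stood at -0.62 ± 0.18 and the co-chaperone Dnajb1 at -0.27 ± 0.0701. The authors' deposited table calls these 3 lower. Chaperones of the endoplasmic reticulum were lower by -0.10 with 11 of 15 below 0 (adjusted p = 0.00338; adjusted p = 0.41 with an estimated correlation), and 1 passed adjusted over the list alone. That was Hspa5, the main chaperone of that compartment, at -0.26 ± 0.0662.

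Clock genes had 13 of 16 members above 0 (adjusted p = 0.000212; adjusted p = 0.41 with an estimated correlation). None passed over all genes, and 5 were higher and 1 lower when adjusted over the list alone. Dbp, a clock output factor, stood at 144 ± 8.02 CPM after amphetamine and 90.4 ± 15.7 CPM after saline, a log2 fold change of 0.67 ± 0.151, and Nr1d2, a clock repressor, had one of 0.30 ± 0.0719. The clock mean was 0.28 without saline control library 5. Microglial genes were higher by 0.26 with 10 of 11 above 0 (adjusted p = 0.000627; adjusted p = 0.41 with an estimated correlation), and by 0.15 without saline control library 5. Glucocorticoid-induced genes, which follow adrenal stress hormone, were lower by -0.28 (adjusted p = 0.0406; adjusted p = 0.746 with an estimated correlation). That call ended without amphetamine control library 1 (-0.22), 2 (-0.25) or 4 (-0.25), the mean was -0.45 without saline control library 3, and it turned to 0.11 without saline control library 5, whose glucocorticoid score was 6.02 against 4.21 in the next library of its group.

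Markers of neighbouring tissue differed between these groups. Ependymal genes had 10 of 10 members below 0 (adjusted p = 5.21e-08; adjusted p = 0.368 with an estimated correlation), 7 of them lower adjusted over the list alone. Tekt1, a cilium protein, stood at 1.47 ± 0.375 CPM against 2.90 ± 0.322 CPM. Pallidal and septal neuron genes were lower by -0.49 with 8 of 9 below 0 (adjusted p = 8.47e-05; adjusted p = 0.368 with an estimated correlation), among them Dlk1, an imprinted Notch-related gene of ventral forebrain, at -0.97 ± 0.206. Cortical projection neuron genes had 12 of 12 members above 0 (adjusted p = 8.47e-05; adjusted p = 0.41 with an estimated correlation), and their mean was 0.61 without saline control library 3. Astrocyte genes were lower by -0.17 with 8 of 10 below 0 (adjusted p = 0.00338; adjusted p = 0.368 with an estimated correlation). Choroid plexus genes were lower by -0.50 (adjusted p = 0.0228; adjusted p = 0.589 with an estimated correlation) but not called without saline control library 5 (-0.44). Blood genes were lower by -0.65 (adjusted p = 0.0309; adjusted p = 0.589 with an estimated correlation), a call that ended without amphetamine control library 2 (-0.59) or 4 (-0.47) or saline control library 2 (-0.40) or 5 (-0.63). Hypothalamic neuron genes, a list added after the data were seen, had scores of -1.55 ± 0.916 against -0.15 ± 1.43 (difference -1.41, exact permutation p = 0.103).

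Acetylcholine genes bear on the question of striatal cholinergic interneurons that the study names in its title. Markers of cholinergic neurons were lower by -0.31 with 10 of 11 below 0 (adjusted p = 0.0475; adjusted p = 0.693 with an estimated correlation). The call ended without amphetamine control library 3 (-0.09) or 5 (-0.32) or saline control library 1 (-0.27), 3 (-0.24), 4 (-0.22) or 5 (-0.34), and the mean was -0.48 without saline control library 2. Chat, the enzyme that makes acetylcholine, stood at 17.8 ± 5.11 CPM after amphetamine and 19.4 ± 5.49 CPM after saline (n = 5 each), a log2 fold change of -0.13 ± 0.337. Slc18a3, which loads acetylcholine into vesicles, had -0.27 ± 0.311 and Slc5a7, which takes up choline, -0.15 ± 0.284. With the 3 neighbouring-tissue covariates, the cholinergic mean turned to 0.21. Acetylcholine receptor and esterase genes were not called (mean -0.06, adjusted p = 0.954). The means of GABAergic interneuron (0.07), glutamate receptor (0.03), neuropeptide (-0.13), interferon-induced (-0.04), thalamic (-0.14), oligodendrocyte (-0.01), oligodendrocyte precursor (-0.09) and vascular (0.01) genes were not called either, nor were those of mitochondrial (0.01), ribosomal (-0.04) and respiratory chain (0.03) genes. Interferon-induced genes were called without saline control library 5 (-0.21), and ribosomal genes without saline control library 3 (-0.07).

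Of 21513 genes tested in control mice, edgeR called 1, and 2546 had an unadjusted p under 0.05 where 1076 are expected by chance. The remaining genes with the smallest p were Gm43210 at -1.60 ± 0.272, Gm19410 at 1.31 ± 0.224, Susd1 at 0.49 ± 0.0883 and Rassf3 at 0.48 ± 0.088, with adjusted p of 0.0843, 0.0843, 0.0868 and 0.0868. The authors' deposited table for this comparison calls 795 genes, 420 higher and 375 lower. Every one of the 795 had the same sign here, which is not independent support, since both fits use the same mice. Of these genes 736 had an unadjusted p under 0.05 by edgeR, and the median adjusted p of the 795 was 0.232. In the authors' deposited table Plcd4 has a log2 fold change of -0.65 with an adjusted p of 6.27e-16. The Plcd4 call ended, at a nearly constant fold change, without amphetamine control library 1 (adjusted p = 0.0603), 2 (0.0793), 3 (0.0519) or 5 (0.0678), and the count of called genes was 0 to 4 on leaving out single libraries, with 4 without saline control library 5 and 2 without saline control library 1, 2 or 4. The count was 207 with DESeq2 and 630 with limma voom, was 183 without the 4 libraries that stand apart, and 0 with the 3 neighbouring-tissue covariates, the last 2 settings added after the data were seen.

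**Figure D2:**
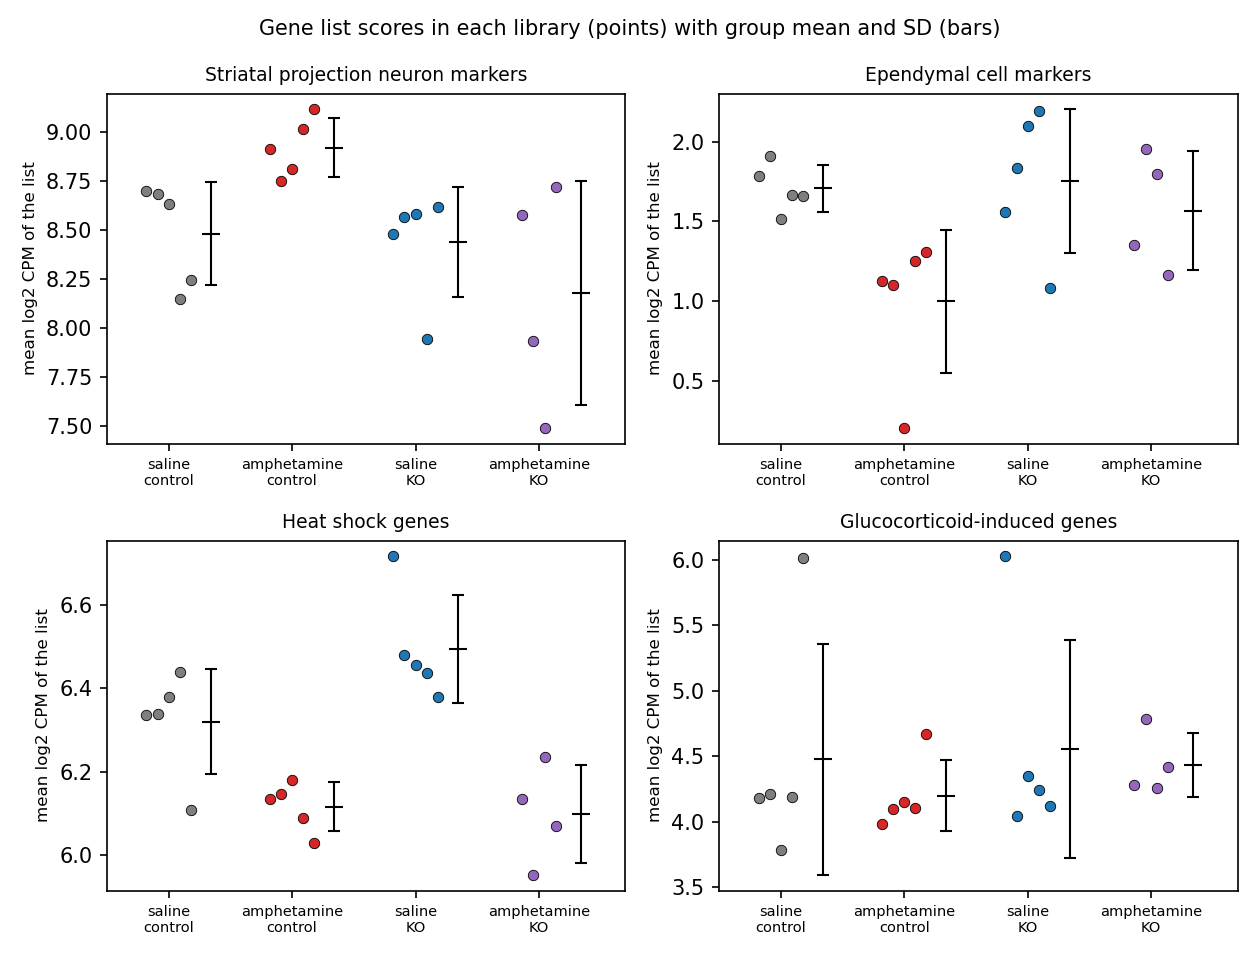
Mean log2 CPM of 4 gene lists in each library (points), with group mean and SD (bars), in the 4 groups. Heat shock scores averaged 6.12 and 6.10 after amphetamine against 6.32 and 6.49 after saline, and the glucocorticoid score stood at 6.02 in saline control library 5 and 6.03 in saline knockout library 1.

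The same dose was then compared with saline in the prefrontal D2 receptor knockout mice. Chaperone genes were again lower after amphetamine, with a mean of -0.40 over heat shock genes and -0.27 over chaperones of the endoplasmic reticulum. Neuropeptide precursors, from which neurons cut their peptide transmitters, were lower by a mean of -0.38, and clock genes were higher by 0.20. Genes of striatal projection neurons were lower by -0.26, and this difference rested on few libraries. Col6a2 (ENSMUSG00000020241.14, chromosome 10, 76431596 to 76459464), a collagen VI chain of the extracellular matrix, was the 1 gene that passed across all genes, rising from 9.33 ± 1.41 CPM (SD, n = 5) to 15.6 ± 1.71 CPM (n = 4), a log2 fold change of 0.74 ± 0.107 (SE) with an adjusted p of 0.0217 by edgeR.

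Heat shock genes had 14 of 14 members below 0, with scores of 6.10 ± 0.118 (SD, n = 4) against 6.49 ± 0.13 (n = 5) (camera, adjusted p = 1.31e-15). This call held with an estimated correlation (adjusted p = 0.0363 with an estimated correlation) and by fry (0.000369), and 12 members were lower adjusted over the list alone while none passed over all genes. The adjusted exact permutation p of the score was 0.0794. Hspa8 went from 1690 ± 39.3 to 1317 ± 51.6 CPM, a log2 fold change of -0.36 ± 0.0624 with an adjusted p of 0.0648. Stip1 and Ahsa1, which serve the chaperone Hsp90, stood at -0.43 ± 0.0834 and -0.39 ± 0.0681, and Hsph1, a nucleotide exchange factor of Hsp70, at -0.60 ± 0.131. Chaperones of the endoplasmic reticulum had 15 of 15 members below 0 (adjusted p = 2.75e-11; adjusted p = 0.0363 with an estimated correlation; fry 0.000416), with 10 lower adjusted over the list alone. Hsp90b1, the Hsp90 of that compartment, went from 490 ± 23.1 to 366 ± 14.6 CPM (log2 fold change -0.42 ± 0.0706, adjusted p = 0.0648). Calr, a calcium-binding chaperone, had -0.41 ± 0.0771 and Hspa5 -0.35 ± 0.0705. The authors' deposited table calls 4 heat shock genes and 4 endoplasmic reticulum chaperones lower.

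Neuropeptide precursors had 12 of 13 members below 0 (adjusted p = 7.72e-05; adjusted p = 0.21 with an estimated correlation; fry 0.042), with 6 lower adjusted over the list alone and none over all genes. Their call ended without the 5 libraries farthest on the principal components (-0.23, adjusted p = 0.0563). Hypothalamic neuron scores, from the list added after the data were seen, were lower too (difference -1.01, exact permutation p = 0.0238). Saline knockout library 3 had the highest neuropeptide (6.66) and hypothalamic (1.28) scores of its group, and without it the neuropeptide mean was -0.28. Crh, the stress peptide corticotropin-releasing hormone, went from 10.6 ± 1.21 to 6.73 ± 0.683 CPM (log2 fold change -0.65 ± 0.129, adjusted p = 0.104), and the authors' deposited table calls it lower with an adjusted p of 0.00022. Nts, the precursor of neurotensin, had -0.77 ± 0.225, Scg2, a granin of secretory vesicles, -0.44 ± 0.143, and Cartpt, a peptide regulated by psychostimulants, -0.87 ± 0.286. Clock genes had 14 of 16 members above 0 (adjusted p = 0.000547; adjusted p = 0.663 with an estimated correlation), with 2 higher adjusted over the list alone. Per3, a clock repressor, stood at 48.2 ± 4.65 against 35.8 ± 2.57 CPM, a log2 fold change of 0.43 ± 0.0878, and Bhlhe40 at 0.38 ± 0.106.

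Direct-pathway markers were lower by -0.37 (adjusted p = 0.00701; adjusted p = 0.649 with an estimated correlation), with 2 of 8 lower adjusted over the list alone. They included Tac1, the substance P precursor, at -0.71 ± 0.253, and Pdyn, the dynorphin precursor, at -0.64 ± 0.224. Indirect-pathway markers were lower by -0.32 (adjusted p = 0.0237; adjusted p = 0.663 with an estimated correlation). Striatal neuron genes at -0.26 (adjusted p = 0.00939; adjusted p = 0.665 with an estimated correlation) and dopamine transduction genes at -0.26 (adjusted p = 0.00332; adjusted p = 0.663 with an estimated correlation) had 13 of 14 and 15 of 16 members below 0. Amphetamine knockout library 3, with the lowest striatal neuron score of all libraries (7.49), ended these 4 calls when left out, the means becoming -0.15, -0.08, -0.03 and -0.04. The indirect-pathway call also ended without saline knockout library 2 (-0.31) or 3 (-0.24), and the striatal neuron call without amphetamine knockout library 2 (-0.18). Without amphetamine knockout library 1 the striatal and dopamine means were -0.39 and -0.40, and without library 4 -0.44 and -0.42. Leaving out the 4 libraries that stand apart, as chosen after the data were seen, turned the striatal neuron mean to 0.24, a call in the opposite direction (adjusted p = 0.00639). It turned the dopamine mean to 0.19, the indirect-pathway mean to 0.12 and the direct-pathway mean to 0.02, none of them called.

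Immediate early factors (mean 0.03, adjusted p = 0.742) and activity effectors (0.00, adjusted p = 0.755) were not called in knockout mice with all libraries. Without amphetamine knockout library 2 the early factors were called at 0.21 (adjusted p = 0.00707), the mean found in control mice. Without the 4 libraries that stand apart they were called at 0.34 (adjusted p = 8e-06) and the effectors at 0.22 (0.0113). Leaving out amphetamine knockout library 4 turned the means to -0.10 for the early factors and -0.08 for the effectors. Fos had a log2 fold change of 0.03 ± 0.179, Arc -0.02 ± 0.295, Npas4 -0.12 ± 0.237 and Egr1 0.12 ± 0.212. Cholinergic neuron genes were lower by -0.48 with 11 of 11 below 0 (adjusted p = 0.00171; adjusted p = 0.663 with an estimated correlation), but not called without amphetamine knockout library 3 (-0.10). Chat stood at 16.7 ± 9.11 CPM (SD, n = 4) against 19.2 ± 0.889 CPM (n = 5), a log2 fold change of -0.20 ± 0.358 that was 0.13 without amphetamine knockout library 3, with Slc18a3 at -0.52 ± 0.332 and Slc5a7 at -0.35 ± 0.302. Acetylcholine receptor and esterase genes were not called (mean 0.14, adjusted p = 0.154), but were without saline knockout library 4 (0.20), and had a mean of 0.05 without saline knockout library 3.

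Genes of energy supply and translation also differed in knockout mice. Nuclear respiratory chain genes were lower by -0.17 with 79 of 80 below 0 (adjusted p = 1.23e-11; adjusted p = 0.663 with an estimated correlation), and by -0.05 without saline knockout library 3. Ribosomal protein genes were lower by -0.16 with 79 of 82 below 0 (adjusted p = 1.23e-08; adjusted p = 0.663 with an estimated correlation), a call that ended at -0.01 without that library, whose ribosomal score was 7.66 against 6.997 in the next library of its group. Mitochondrially encoded transcripts were lower by -0.19 (adjusted p = 0.0189; adjusted p = 0.663 with an estimated correlation), a call that ended without amphetamine knockout library 3 (-0.15) or saline knockout library 3 (-0.12). Cortical neuron genes were higher by 0.69 (adjusted p = 0.0116; adjusted p = 0.663 with an estimated correlation). Their call ended without amphetamine knockout library 3 (0.30) or 4 (0.52) or saline knockout library 3 (0.49), and the mean was 1.16 without amphetamine knockout library 2. Choroid plexus genes were not called (0.66, adjusted p = 0.0663), with 6 higher adjusted over the list alone. They were called without amphetamine knockout library 1 (0.88), 3 (0.78) or 4 (0.99) or saline knockout library 4 (0.72), and had a mean of -0.03 without amphetamine knockout library 2. Ependymal genes (-0.19, adjusted p = 0.138) were called without amphetamine knockout library 2 (-0.32) or saline knockout library 5 (-0.35). Microglial genes (-0.11, adjusted p = 0.0663) were called without amphetamine knockout library 1 (-0.15) or 4 (-0.14) or saline knockout library 4 (-0.16) or 5 (-0.14). Hypothalamic neuron genes, a list added after the data were seen, had scores of -0.05 ± 0.604 against 0.96 ± 0.357 (difference -1.012, exact permutation p = 0.0238).

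In knockout mice 2600 of 21513 genes had an unadjusted p under 0.05. After Col6a2 the smallest p belonged to Hsp90b1, Hspa8, Ahsa1 and Txnl4a, a splicing factor at -0.47 ± 0.084, all with an adjusted p of 0.0648. The authors' deposited table calls 131 genes, 80 higher and 51 lower. All 130 of these that were tested here had the same sign, again in the same mice, with a median adjusted p of 0.278 by edgeR. The Col6a2 call ended without amphetamine knockout library 1 (adjusted p = 0.074), 3 (0.0794) or 4 (0.0901) or saline knockout library 1 (0.0788) or 4 (0.119), and also without the 4 libraries that stand apart (0.0634) or the 5 farthest on the principal components (0.0568). Counts of called genes ran from 0 to 3 on leaving out single libraries, with 3 without saline knockout library 3. The count was 98 with DESeq2, 203 with limma voom, and 0 with only the compared groups in the fit or with the 3 neighbouring-tissue covariates.

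Whether the response to amphetamine differed between genotypes was tested as an interaction, the response in knockout minus that in control mice. Lists called by camera included striatal projection neuron genes (-0.69) and dopamine transduction genes (-0.56). Both were higher after amphetamine in control mice and, with all libraries, lower in knockout mice. The interaction was also called for heat shock genes (-0.19, from means of -0.20 in control and -0.40 in knockout mice) and chaperones of the endoplasmic reticulum (-0.17, from -0.10 and -0.27). The same held for microglial (-0.37, from 0.26 and -0.11), ependymal (0.52, from -0.71 and -0.19) and choroid plexus genes (1.16, from -0.50 and 0.66). Heat shock scores averaged 6.10 in knockout and 6.12 in control mice after amphetamine, against 6.49 and 6.32 after saline. Their interaction thus arose mainly under saline, where saline control library 5 (6.11) was lowest and saline knockout library 1 (6.72) highest. No list was called in the interaction with an estimated correlation. No single gene was called.

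Striatal neuron genes had 14 of 14 members below 0 in this test (camera, adjusted p = 1.11e-08; adjusted p = 0.473 with an estimated correlation) and dopamine transduction genes 15 of 16 (adjusted p = 3.18e-07; adjusted p = 0.473 with an estimated correlation). Direct-pathway and indirect-pathway markers had the same adjusted p of 0.00163 (adjusted p = 0.473 and 0.478 with an estimated correlation). Microglial genes had an adjusted p of 8.15e-05 (adjusted p = 0.473 with an estimated correlation), heat shock genes one of 0.000745 (adjusted p = 0.478 with an estimated correlation) and endoplasmic reticulum chaperones one of 0.00106 (adjusted p = 0.473 with an estimated correlation). Without amphetamine knockout library 3 the dopamine mean was -0.34, the direct-pathway mean -0.34 in place of -0.56, and the indirect-pathway mean -0.36 in place of -0.61. Drd1 differed by -0.84 ± 0.333, Tac1 by -0.96 ± 0.345, Adora2a, the adenosine receptor of indirect-pathway neurons, by -0.96 ± 0.43, and Rgs4 by -0.69 ± 0.264, all with an adjusted p of at least 0.519 by edgeR. Among heat shock genes Hsph1 differed by -0.54 ± 0.179 and Ahsa1 by -0.26 ± 0.0931. Ctss, a lysosomal protease of microglia, differed by -0.50 ± 0.177. Without the 4 libraries that stand apart, the striatal, dopamine, direct-pathway, indirect-pathway, microglial and ependymal lists were not called. The striatal mean was -0.13 and the microglial mean -0.10 there, whereas heat shock genes (-0.14) and endoplasmic reticulum chaperones (-0.11) were still called. Those 4 include saline control library 5 but not saline knockout library 1. On leaving out only saline control library 5, the heat shock mean was -0.26 in control mice. On leaving out only saline knockout library 1, it was -0.34 in knockout mice, and the heat shock interaction was -0.14.

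Of 15 lists called in the interaction, 6 lost their call when some single library was left out and 9 did not. Choroid plexus (adjusted p = 0.00106) and neuropeptide (0.0176) genes had adjusted p = 0.478 with an estimated correlation, immediate early factors (0.0266) and mitochondrial transcripts (0.0422) adjusted p = 0.672, and activity effectors (0.0422) adjusted p = 0.663. Ribosomal (0.000745), ependymal (0.002) and respiratory chain (9.06e-10) genes had adjusted p = 0.744, 0.624 and 0.629 with an estimated correlation. Choroid plexus genes (1.16) were not called without amphetamine knockout library 2 (0.47), whose choroid score was 3.25. Ribosomal protein genes (-0.12) turned to 0.03 without saline knockout library 3, and neuropeptides (-0.25) were not called without saline control library 1 (-0.20) or saline knockout library 3 (-0.15). Immediate early factors (-0.18) were at 0.00 without amphetamine knockout library 2, and not called, at -0.18 to -0.13, without amphetamine control library 3 or 4, saline control library 3, 4 or 5 or saline knockout library 1, 3 or 5. They were at -0.32 without amphetamine knockout library 4 and at -0.29 without saline control library 2. Activity effectors (-0.19) were at -0.09 without amphetamine knockout library 2 and not called, at -0.18 to -0.14, without amphetamine control library 2, 3 or 4, amphetamine knockout library 3, saline control library 3 or 4 or saline knockout library 3 or 5. Mitochondrial transcripts (-0.20) were at -0.32 without amphetamine control library 1 and not called, at -0.21 to -0.11, without amphetamine control library 3, 4 or 5, amphetamine knockout library 1 or 3, saline control library 1, 3 or 4 or saline knockout library 2 or 3. Ependymal genes (0.52) were at 0.33 without amphetamine control library 3, and respiratory chain genes (-0.21) at -0.08 without saline knockout library 3.

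The edgeR count for the interaction was 0 of 21513 genes, with 1991 at an unadjusted p under 0.05, 14 called by DESeq2 and 0 by limma voom. Col6a2 had the smallest p (0.80 ± 0.148, adjusted p = 0.451), followed by Zfp185 at 1.93 ± 0.372, Tsku, a secreted inhibitor of growth factors, at 1.00 ± 0.211, Nrbp2 at 0.49 ± 0.107 and Spaca6 at 0.72 ± 0.162.

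The amphetamine responses of both genotypes, which share no libraries, had a correlation of 0.122 across the 21513 genes, where genes are not independent replicates, and 11279 genes had the same sign. Over 12166 genes with a mean of at least 5 CPM the correlation was 0.242. It lay at 0.242 without amphetamine knockout library 2, 0.224 without saline control library 5, 0.0564 without saline knockout library 4, 0.0540 without amphetamine control library 3 and 0.0311 without amphetamine knockout library 4. Among 18803 genes with an adjusted p in both of the authors' deposited tables, 419 and 76 were called higher in control and knockout mice with 2 in common (Gm19410 and Scel), where 1.69 would be shared by independent lists. For the lower calls, 374 and 51, the authors' deposited tables share 4 (H1f2, Hspa5, Hspa8 and Nrip2), where 1.01 would be, and 0 genes were called in opposite directions. Over the 795 genes that the authors' deposited table calls in control mice, the knockout response had 0.233 of the slope of the control response here, and 540 had the same sign. Over the 130 genes that it calls in knockout mice, the control response had 0.180 of the slope of the knockout response, and 83 had the same sign. Choosing genes by 1 of the responses lowers such a slope by itself, so these values do not compare the size of the responses.

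**Figure D3:**
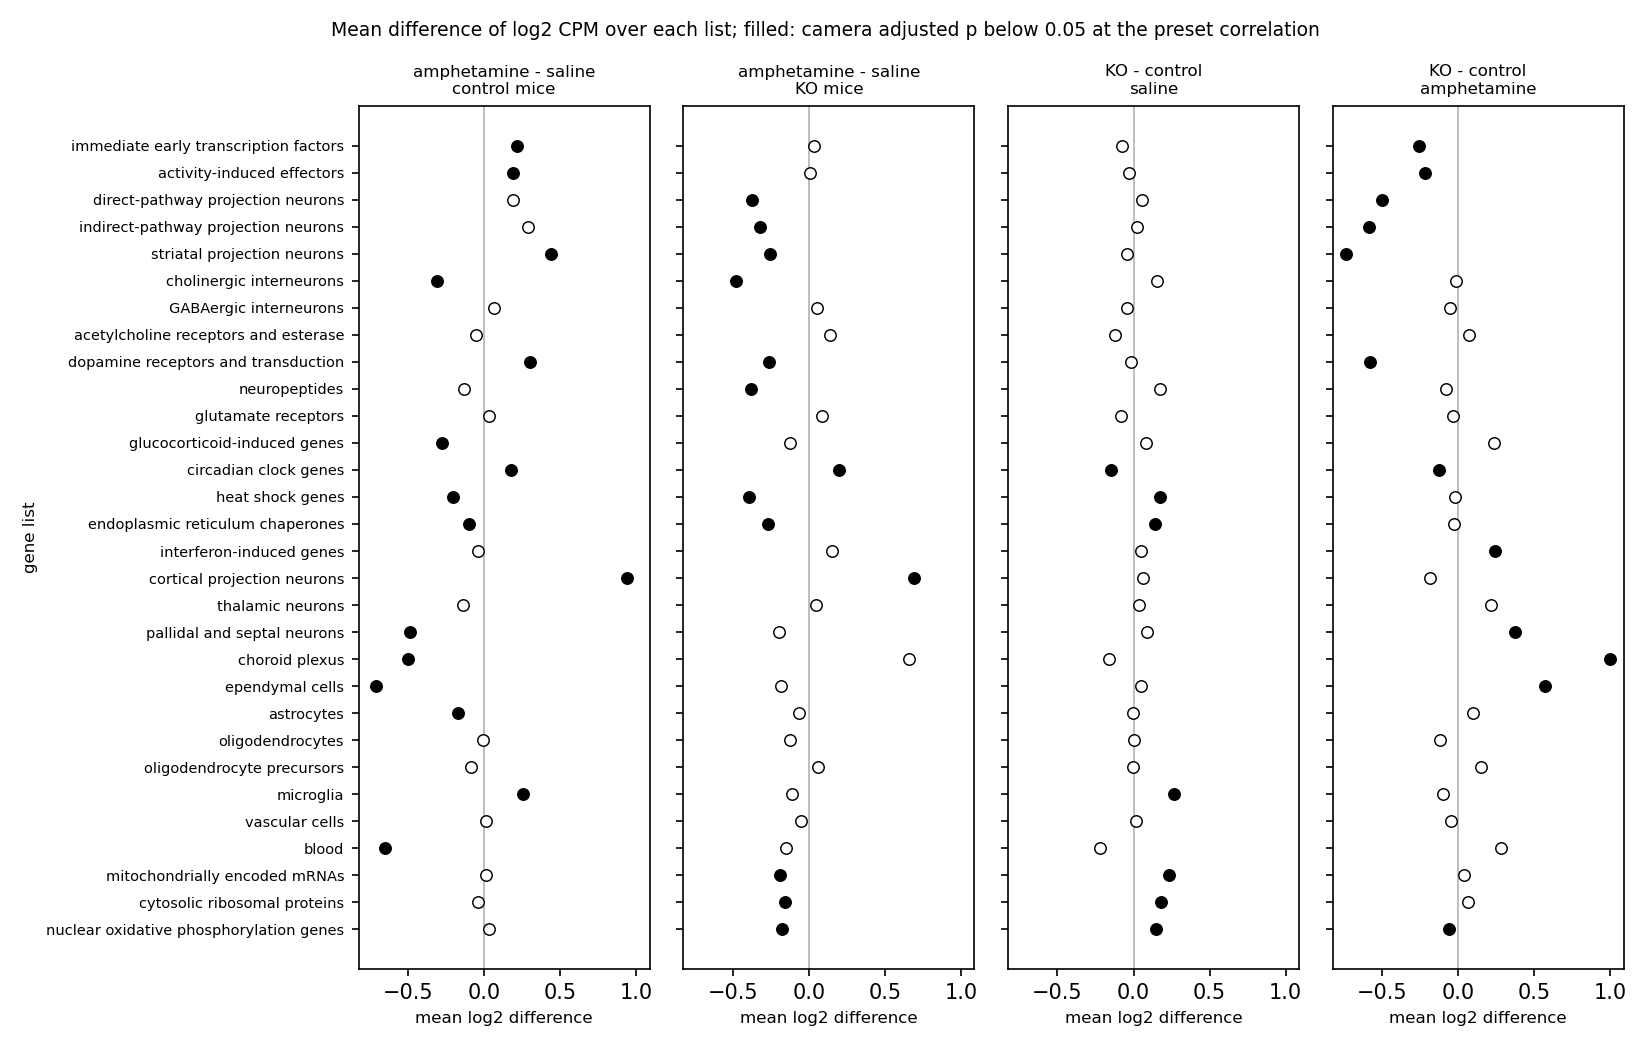
Mean difference of log2 CPM (horizontal axis) for each of the 30 gene lists (vertical axis) in 4 comparisons, with filled points for lists called by camera at the preset correlation. Striatal projection neuron genes lie at 0.44 for amphetamine in control mice, -0.26 in knockout mice and -0.74 for knockout against control under amphetamine.

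Under saline, knockout and control mice were compared to see what the prefrontal knockout alone does in the striatum. By camera at the preset correlation, chaperone genes were higher in knockout mice, by a mean of 0.17 over heat shock genes and 0.14 over those of the endoplasmic reticulum. No list in this comparison was called with an estimated correlation or by exact permutation of the scores, where the smallest adjusted p was 0.476. Microglial genes were higher by 0.27. Ribosomal protein genes, respiratory chain genes and mitochondrially encoded transcripts were higher by 0.18, 0.15 and 0.24, with saline knockout library 3 carrying much of the first 2. Projection neuron and cholinergic genes were not called with all libraries and no covariates.

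Heat shock genes had 14 of 14 members above 0, with scores of 6.49 ± 0.13 (SD, n = 5) against 6.32 ± 0.125 (n = 5) (camera, adjusted p = 2.19e-05; adjusted p = 0.469 with an estimated correlation). Chaperones of the endoplasmic reticulum had 14 of 15 above 0 (adjusted p = 3.2e-05; adjusted p = 0.469 with an estimated correlation). Hspe1, a mitochondrial co-chaperone, stood at 0.30 ± 0.104, Ahsa1 at 0.20 ± 0.0638, Hspa8 at 0.14 ± 0.0585 and Xbp1, a transcription factor of the unfolded protein response, at 0.22 ± 0.0799. No member passed over all genes or adjusted over the list alone. Without the 2 saline libraries with high glucocorticoid-induced genes, left out after the data were seen, the heat shock mean was 0.07 and not called. Microglial genes had 11 of 11 above 0 (adjusted p = 4.33e-05; adjusted p = 0.469 with an estimated correlation), with 2 higher adjusted over the list alone, and a mean of 0.16 without saline control library 5. They were not called without the 4 libraries that stand apart (0.11, adjusted p = 0.0501). Ctss stood at 89.5 ± 20.8 against 66.5 ± 4.75 CPM (log2 fold change 0.43 ± 0.121) and C1qa, a complement subunit, at 0.39 ± 0.159.

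Ribosomal protein genes had 81 of 82 members above 0 (adjusted p = 4.41e-13; adjusted p = 0.942 with an estimated correlation) and a mean of 0.04 without saline knockout library 3. Respiratory chain genes had 78 of 80 above 0 (adjusted p = 1.15e-09; adjusted p = 0.98 with an estimated correlation) and were not called without that library (0.02). Mitochondrially encoded transcripts had 13 of 13 above 0 (adjusted p = 0.000618; adjusted p = 0.942 with an estimated correlation). Clock genes were lower by -0.15 with 13 of 16 below 0 (adjusted p = 0.00239; adjusted p = 0.942 with an estimated correlation), but not called without saline control library 5 (-0.05). Glucocorticoid-induced genes were not called (0.08, adjusted p = 0.923), and the 2 groups each held 1 library with a high score. Their mean was 0.46 without saline control library 5 and -0.29 without saline knockout library 1, both called.

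Cholinergic neuron genes had a mean of 0.16 (adjusted p = 0.456) and striatal projection neuron genes one of -0.04 (adjusted p = 0.878). In settings added after the data were seen the striatal mean was called in opposite directions, at 0.19 (adjusted p = 0.0104) with the 3 neighbouring-tissue covariates and at -0.14 (0.0419) without the 5 libraries farthest on the principal components, and the covariates also gave called means of 0.28 for indirect-pathway and 0.17 for dopamine transduction genes. Chat stood at 19.2 ± 0.889 CPM in knockout and 19.4 ± 5.49 CPM in control mice (n = 5 each). For single genes the edgeR count was 0 of 21513, with 1708 at an unadjusted p under 0.05, 0 called by DESeq2 on all libraries or on the 2 groups, and 0 by limma voom. The smallest p-values, all with an adjusted p of 0.614, belonged to Spaca6, a sperm membrane protein in its known role, at 7.95 ± 0.732 against 11.6 ± 1.26 CPM (log2 fold change -0.54 ± 0.111), Col6a2 at -0.49 ± 0.102, Gm47765 at -1.66 ± 0.358, Tmem30b at -1.86 ± 0.412 and Ssc5d at -0.66 ± 0.16. The authors' deposited table calls Spaca6 (chromosome 17, 18047420 to 18063271) alone, with an adjusted p of 0.0243.

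Under amphetamine, knockout mice were compared with control mice. Camera at the preset correlation called the lists named next, and no list was called with an estimated correlation. Genes of striatal projection neurons were lower in knockout mice by a mean of -0.74, indirect-pathway markers by -0.59, direct-pathway markers by -0.50 and dopamine transduction genes by -0.58. Choroid plexus genes, from the tissue that makes cerebrospinal fluid, were higher by 1.00, ependymal genes by 0.57 and pallidal and septal genes by 0.37. Immediate early factors were lower by -0.26 and activity effectors by -0.22. The spread was wide in the 4 knockout mice: the striatal neuron score was 8.18 ± 0.571 (SD, n = 4) against 8.92 ± 0.149 (n = 5), and library 3 had the lowest score at 7.49 and library 2 the next at 7.94.

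All 14 striatal neuron genes were below 0, and 14 were lower adjusted over the list alone while none passed over all genes (camera, adjusted p = 6.29e-14; adjusted p = 0.389 with an estimated correlation). Examples are Rasd2 at 240 ± 99.6 against 422 ± 60.9 CPM (log2 fold change -0.82 ± 0.233), Rarb, a retinoic acid receptor, at -0.73 ± 0.216, and Pde1b, which breaks down cyclic nucleotides, at -0.70 ± 0.21. Dopamine transduction genes had 15 of 16 below 0 (adjusted p = 8.46e-11; adjusted p = 0.389 with an estimated correlation), 13 lower adjusted over the list alone. They included Drd2 at -1.02 ± 0.276 (adjusted p = 0.223), Rgs4 at -0.69 ± 0.194 and Drd1 at -0.79 ± 0.245. Indirect-pathway markers (adjusted p = 9.55e-05; adjusted p = 0.389 with an estimated correlation) had 4 of 8 lower adjusted over the list alone, with Adora2a at -0.90 ± 0.317. Direct-pathway markers (adjusted p = 0.000666; adjusted p = 0.389 with an estimated correlation) had 2, with Tac1 at 160 ± 69.0 against 269 ± 41.3 CPM, a log2 fold change of -0.75 ± 0.254. Exact permutation tests of the scores gave an adjusted p of 0.0476, from the smallest p the design can give, for the striatal, dopamine and indirect-pathway lists, and for thalamic (0.22) and oligodendrocyte precursor (0.15) genes, which camera did not call (adjusted p = 0.288 and 0.111).

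Without amphetamine knockout library 3 the means were -0.35 for dopamine transduction, -0.34 for indirect-pathway and -0.28 for direct-pathway genes, all still called. The neighbouring-tissue scores moved with these lists: with the 3 of them as covariates, added after the data were seen, the striatal neuron mean was -0.17 and called, while the dopamine (-0.10), indirect-pathway (-0.09) and direct-pathway (-0.11) lists were not. Without the 4 libraries that stand apart, the striatal mean was -0.27 and the dopamine mean -0.14, both called, and direct-pathway genes (-0.14) were not.

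Choroid plexus genes had 12 of 12 members above 0, 10 of them higher adjusted over the list alone (adjusted p = 0.000233; adjusted p = 0.443 with an estimated correlation), and were not called without amphetamine knockout library 2 (0.31). Ependymal genes had 10 of 10 above 0 (adjusted p = 3.94e-05; adjusted p = 0.443 with an estimated correlation), with 4 higher adjusted over the list alone and a mean of 0.37 without amphetamine control library 3. Their call ended without the 4 libraries that stand apart (0.26), without the 5 farthest on the principal components (0.06) and with the 3 covariates (0.23), and the choroid plexus call without the 4 (0.16). Pallidal and septal genes had 8 of 9 above 0 (adjusted p = 0.00332; adjusted p = 0.443 with an estimated correlation), with 3 higher adjusted over the list alone, and means of 0.23 without amphetamine control library 3 and 0.24 without amphetamine knockout library 2. Their call ended without the 5 libraries (0.18) and with the 3 covariates (0.06). Zic2, a zinc finger factor of septum, stood at 34.9 ± 8.4 against 20.8 ± 2.94 CPM. Hypothalamic neuron genes had scores of -0.05 ± 0.604 against -1.55 ± 0.916 (difference 1.498, exact permutation p = 0.0317, list added after the data were seen).

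Immediate early factors had 21 of 24 members below 0 (adjusted p = 0.00027; adjusted p = 0.62 with an estimated correlation), with 1, Ier5 at -0.71 ± 0.171, lower adjusted over the list alone. They were not called without amphetamine knockout library 2 (-0.07), and the mean was -0.39 without library 4. It turned to 0.04 without the 4 libraries that stand apart and to 0.16 with the 3 covariates. Activity effectors had 18 of 24 below 0 (adjusted p = 0.000851; adjusted p = 0.443 with an estimated correlation), and a mean of -0.12 without amphetamine knockout library 2. They were not called without the 4 libraries that stand apart (-0.02) or with the 3 covariates (0.03). Homer1, a scaffold of glutamate synapses, stood at -0.54 ± 0.161. Clock genes were lower by -0.12 (adjusted p = 0.0097; adjusted p = 0.626 with an estimated correlation) and not called without amphetamine control library 5 (-0.09). Interferon-induced genes were higher by 0.24 with 17 of 18 above 0 (adjusted p = 0.0302; adjusted p = 0.787 with an estimated correlation), a call that ended without amphetamine control library 2 (0.17) or 4 (0.22) or amphetamine knockout library 1 (0.16) or 2 (0.21). Respiratory chain genes were lower by -0.06 (adjusted p = 0.00863; adjusted p = 0.84 with an estimated correlation) and not called without amphetamine control library 1 (-0.03).

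Cholinergic neuron genes had a mean of -0.01 (adjusted p = 0.775), which became 0.36 and called without amphetamine knockout library 3. That library had a cholinergic score of 2.59 and a Slc18a3 level of 2.13 CPM, against 8.15 CPM in the next library of its group. Heat shock genes (-0.02, adjusted p = 0.437) and endoplasmic reticulum chaperones (-0.03, adjusted p = 0.5) were not called. For single genes the edgeR count was 0 of 21513, with 2749 at an unadjusted p under 0.05, 106 called by DESeq2 on all libraries, 723 by DESeq2 on the 2 groups alone (an added setting) and 0 by limma voom. The smallest p-values, with an adjusted p of 0.220 each, belonged to Cd36, a fatty acid receptor, at 1.75 ± 0.343, Zfp423 at 0.76 ± 0.151, Gm8281 at 1.07 ± 0.214, Gm32444 at 0.61 ± 0.122 and Crocc2, a ciliary rootlet gene, at 1.27 ± 0.262.

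The effect of the knockout under saline and the effect of amphetamine in control mice share the saline control libraries. Their correlation across 21513 genes was 0.171. Libraries simulated without group differences, the controls drawn anew as well, shared controls in the same way. They gave 0.4999 on average (SD 0.0101, from 0.475 to 0.524 in 100 simulations), a positive value that follows from the shared controls. Genes were drawn independently there, so the narrow range leaves out the correlation between real genes. A lower observed value therefore does not show opposing effects. The observed covariance was 0.0143 against a simulated 0.0299, a difference of -0.0156. With the control libraries split so that the comparisons shared none, the correlation averaged -0.148 over 20 splits, from -0.351 to 0.00470.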

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

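The tests of neighbouring tissue, of single libraries and of the glucocorticoid-induced genes were chosen after the results were seen. The counts over other splits of the mice were planned, except those with DESeq2 on the groups compared.

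Single libraries lay far from the rest of their group, by a ratio of gap to range, in 22 of 184 groups of values (46 measures), where chance gives about 1 in 20 groups, or 9.2. Amphetamine knockout library 3 had a low share of counts in its 10 highest genes (6.11%) and a low Slc18a3 level (2.13 CPM). Amphetamine control library 3 had low scores for cholinergic (2.87), thalamic (3.71), pallidal and septal (3.91) and ependymal (0.20) genes and a low Slc18a3 level (3.68 CPM). Amphetamine control library 1 was low for immediate early factors (4.26) and Npas4 (14.6 CPM) and high for endoplasmic reticulum chaperones (6.13). Saline knockout library 3 was high for ribosomal (7.66) and respiratory chain (6.84) genes and low for glutamate receptor (5.95) and thalamic (3.74) genes. Saline knockout library 4 was low for striatal neuron genes (7.94) and Drd1 (104 CPM), library 1 for Slc18a3 (8.62 CPM), and library 2 was high for Slc5a7 (57.3 CPM). Saline control library 2 was low for pallidal and septal genes (4.60). Glucocorticoid-induced genes were high in saline control library 5 (6.02), saline knockout library 1 (6.03) and amphetamine control library 5 (4.67).

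The response to amphetamine differed between genotypes for 15 lists by camera at the preset correlation, and for 0 of them with an estimated correlation. The response in knockout minus that in control mice was below 0 for immediate early factors (-0.18), activity effectors (-0.19), direct-pathway (-0.56), indirect-pathway (-0.61), striatal neuron (-0.69), dopamine transduction (-0.56), neuropeptide (-0.25), heat shock (-0.19), endoplasmic reticulum chaperone (-0.17), microglial (-0.37), mitochondrial (-0.20), ribosomal (-0.12) and respiratory chain (-0.21) genes. It was above 0 for choroid plexus (1.16) and ependymal (0.52) genes. The means in control and knockout mice were -0.20 and -0.40 for heat shock genes, and -0.71 and -0.19, the last not called, for ependymal genes. Of 100 splits, 14 gave as many lists, with up to 18 in another split, so chance is not excluded for the number of lists.

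Striatal neuron genes were higher after amphetamine in control mice and lower in knockout than in control mice under amphetamine. Both were calls of camera at the preset correlation, and neither held with an estimated correlation. In control mice cortical minus ependymal scores differed by 1.65 (SE 0.6), lists picked after their opposite changes were seen. That argues only against an equal change of all neighbouring tissue, and not against a difference in the tissue taken along. Between genotypes (-0.76, SE 0.636) this score left an equal change open. With cortical, choroid plexus and hypothalamic scores as covariates, the genotype difference went from -0.74 (SE 0.223) to -0.17 (SE 0.221). Differences in the tissue taken along are therefore a candidate explanation. Without amphetamine knockout libraries 2 and 3 the genotype difference was -0.27 (SE 0.193). These libraries had the lowest striatal neuron scores of their group (7.94 and 7.49). Leaving them out shrinks the difference whatever its cause, so that value does not bear on the tissue taken along. In control mice the covariates moved 0.44 (SE 0.210) to 0.31 (SE 0.183), which decides neither way. Whether the genotype is the cause of the difference stays open.

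Glucocorticoid-induced genes stood apart in saline control library 5 and saline knockout library 1, by 1.84 (SD 0.162) on the log2 scale. Of 18 measured members, 17 were higher in both than in every other library of their groups, so a few genes do not carry the pattern. Fkbp5, which tunes the glucocorticoid receptor, stood at 174 CPM against 47.0 ± 2.15 CPM in the other saline control mice, and at 113 CPM against 47.3 ± 4.01 CPM in the other saline knockout mice. No cell type or tissue list deviated by as much in both libraries, the largest shared deviation of 17 such lists being -0.50 (SD 0.106, oligodendrocytes). That value and the one of astrocyte genes (0.21, SD 0.0672) still exceeded the spread of the other saline libraries. A difference in cell composition is therefore not ruled out. The design names no group that would account for these 2 mice, and no biological explanation was tested.

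Heat shock genes were lower after amphetamine in both genotypes by camera at the preset correlation. With an estimated correlation only the call in knockout mice held. The adjusted exact permutation p of the score was 0.136 in control and 0.0794 in knockout mice. Cortex, choroid plexus and hypothalamus taken along are argued against as the whole cause. With their scores as covariates the difference was -0.22 (SE 0.0859) in control mice, against -0.20 (SE 0.0703) without them. In knockout mice it was -0.34 (SE 0.0977) against -0.40 (SE 0.0746). Ependymal (-0.71) and pallidal and septal (-0.49) scores, also lower after amphetamine in control mice, were not among the covariates. Other neighbouring tissue is therefore not ruled out. A single deciding library is argued against too, since the smallest differences on leaving out 1 library were -0.17 (SE 0.0735) and -0.34 (SE 0.0665). A response of striatal cells to amphetamine may be the source, as a hypothesis found and tested on the same data. Other causes, such as differences between the groups in handling or time of tissue collection, were not tested. Clock genes were also higher after amphetamine in both genotypes (means 0.18 in control and 0.20 in knockout mice). That leaves the time of collection open and does not tell it from an effect of the drug.

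For amphetamine in control mice, 2 of 100 splits, the real one included, gave as many genes by edgeR (1, highest other 1). As many lists came from 3 of 100 (16, highest other 20), and as many genes by DESeq2 on both groups from 2 of 60 (762, highest other 772). Such counts were uncommon, but other splits reached or passed each of them, so chance is not excluded. In knockout mice 6 of 100 splits gave as many genes by edgeR (1, highest other 6), so chance is not excluded. The same holds for lists, with 50 of 100 splits (13, highest other 20). By DESeq2 on both groups 2 of 60 gave as many genes (124, highest other 176). That share is low, but another split called more genes, so chance is not excluded for that count either.

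For the knockout under saline, 79 of 100 splits gave as many lists (7, highest other 15), and for the knockout under amphetamine 35 of 100 did (12, highest other 18). Chance is not excluded for these list counts. The 723 genes of DESeq2 on both groups were reached by 1 of 60 splits, the real one (highest other 324). That share is the smallest these splits can give, and the setting was added after the data were seen. Chance is therefore less likely for that count but not excluded. Where edgeR called 0 genes, all 100 of 100 splits reach that count by construction, so the splits say nothing about chance. The highest other counts were 1 for the knockout under saline (1708 genes at an unadjusted p under 0.05; 0 by DESeq2 and limma voom), 1 for the knockout under amphetamine (2749; 106 by DESeq2 and 0 by limma voom) and 2 for the interaction (1991; 14 by DESeq2 and 0 by limma voom).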

How the results depend on the processing

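The settings without the 4 libraries that stand apart, without the 5 libraries farthest on the principal components, without 2 saline libraries with high glucocorticoid-induced genes, with 3 neighbouring-tissue covariates and with DESeq2 on the 2 groups compared were chosen after the results were seen. The others were planned.

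The count of 1 called gene for amphetamine in control mice became 207 with DESeq2 on all libraries, 630 with limma voom, 762 with DESeq2 on the groups compared, 75 with only those groups in the edgeR fit, 183 without the 4 libraries, 39 without the 5, 7 without the 2 saline libraries, and 0 with a cortical covariate or the 3 covariates. In knockout mice the count of 1 became 98, 203, 124, 0, 3, 2, 3 and 0 in the same order, 3 with a filter of 1 CPM and 4 with 1 surrogate variable. For the knockout under amphetamine 0 became 106 with DESeq2 on all libraries, 723 with DESeq2 on the groups compared and 1 without the 4 or the 5 libraries, and for the interaction 0 became 14 with DESeq2 on all libraries. For the knockout under saline the count was 0 in each setting run. The cause was not tested. In the simulated data DESeq2 on the groups compared called 32 to 61 unchanged genes against 4 to 7 by edgeR on all libraries. The tool and the libraries fitted differed together there, so these counts do not explain the difference in the real data.

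Leaving out 1 library gave 0 to 4 genes for amphetamine in control mice, 0 to 3 in knockout mice, and 0 to 0 for the other 3 contrasts. The correlation between the responses ran from 0.0311 to 0.242, and was 0.242 for genes of at least 5 CPM. The correlation of the saline knockout effect with the amphetamine effect turned from 0.171 to -0.148 with split controls, which removes the shared libraries.

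As a replicate block, the mouse number in the title gave 1 called gene for amphetamine in control mice and 5 in knockout mice, and the number in the library name gave 0 in both. Over 150 list results the number in the title ended 7 calls and gained 1, with 11 lists in place of 15 in the interaction and 10 in place of 12 for the knockout under amphetamine. Own-number pairs correlated at -0.193 to 0.0598 in control mice and at 0.074 to 0.197 by library name in knockout mice, where 3 of 4 pairs were over 0.1 and 3 correlated best within the pair. A pairing by library name in knockout mice is therefore left open. Mice were not treated as pairs, and under that block Col6a2 was not called (0.81, adjusted p = 0.429).

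Over 150 list results, DESeq2 size factors and a prior count of 0.5 changed 0 calls, an estimated correlation ended 61 and fry 60. The calls at the preset correlation numbered 16, 13, 7, 12 and 15 in the 5 contrasts. Of these, an estimated correlation left 2 and fry 3, all for amphetamine in knockout mice. On leaving out 1 library, 1584 of 1710 list results stayed on their side of the threshold, 71 lost a call in the same direction, 50 gained 1, and 5 that were called before or after changed sign. Another 112 changed sign without being called before or after. The 5 came from lists with ranges of -0.45 to 0.11 for glucocorticoid-induced genes with amphetamine in control mice, -0.29 to 0.46 for these genes with the knockout under saline, -0.23 to 0.36 for cholinergic genes with the knockout under amphetamine, -0.175 to 0.0261 for ribosomal genes in the interaction and -0.319 to 0.000174 for immediate early factors in the interaction.

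Without the 4 libraries, glucocorticoid-induced genes turned to 0.11 for amphetamine in control mice. Direct-pathway (0.0186), indirect-pathway (0.12), striatal neuron (0.24, called) and dopamine (0.19) genes turned for amphetamine in knockout mice, and oligodendrocyte genes (-0.17, called) for the knockout under saline. Immediate early factors turned for the knockout under amphetamine (0.0380) and in the interaction (0.15), as did effectors in the interaction (0.0179). Without the 5 libraries the same lists turned, with these values for the lists of knockout mice and of the knockout under saline, and with 0.12 for glucocorticoid-induced genes in control mice, 0.0646 and 0.18 for the early factors and 0.0467 for effectors in the interaction, and effectors turned for the knockout under amphetamine (0.00751). Without the 2 saline libraries glucocorticoid-induced genes turned to 0.11 in control and 0.25 (called) in knockout mice. With the 3 covariates the early factors (-0.0867), effectors (-0.00902) and cholinergic genes (0.21) turned in control mice, striatal neuron (0.19) and dopamine (0.17) genes for the knockout under saline, both called, and the early factors in the interaction (0.0896). For the knockout under amphetamine the early factors (0.16, called), effectors (0.0316) and respiratory chain genes (0.00522) turned. The cause was not tested.

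Of 315 named gene results, 62 changed sign in some setting, and 0 of these changes had a call by the test used before or after. Depth was 57003408 counts or more per library, and its effect on the calls was not tested.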
